A study of Mus musculus with 4 samples.

How the data were processed

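Gene expression was measured by RNA sequencing of sorted splenic B cells from 10-week-old mice, 2 libraries labelled CD19 DKO and 2 labelled Dfl, called control. Per the labels, libraries were made from total RNA with a NuGEN Ovation kit and read single-end on an Illumina HiSeq. The deposited counts are whole numbers of reads per gene symbol in each library; the authors' processing notes name STAR, featureCounts of Subread 1.4.3-p1 and the mouse build GRCm38, and do not state the strand setting, the annotation release or any filter. The count table holds 17257 genes, of which 1374 had 0 counts in all 4 libraries, and has no immunoglobulin segment or mitochondrial symbols, so those genes were not analysed. The authors' deposited result table gives, for 15883 genes, a signal per library that equals the count divided by 1 size factor per library. The same table deposited by the authors gives a log2 fold change of CD19 DKO over control, whose sign was checked against the counts. It gives a Wald score, the log2 fold change over its standard error, as deposited by the authors. It also gives the p-value of that test and an adjusted p, per the file headers; the authors' notes name DESeq2. In 2772 of its genes the value 2 stands in place of an adjusted p, leaving 13111 with one, and 23 gene symbols had been turned into dates; the date symbols were left out when genes were matched.

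Genes were tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr with its default minimum of 10 counts and a total of 15, and a quasi-likelihood F test of genotype, with p adjusted by Benjamini and Hochberg over 12068 genes and a threshold of 0.05. The common biological coefficient of variation was 0.293 and the prior degrees of freedom were 2.31. CPM values use TMM-scaled library totals. SE was derived from the test, as the absolute log2 fold change over the square root of its F statistic. Ranges after ± are SDs over 2 libraries. Where a group had no counts, the fold is a bound against a floor of 3 counts over the group; where it had 1 to 3 counts, the ratio is given with its exact 95% counting interval. Reads carry no molecular identifiers, so intervals and floors cover counting error only. Counts were also simulated from the libraries' means and sizes, with 1 dispersion trend for both groups. In them 200 genes were changed 2-fold or 4-fold, and a list of 40 more was raised 2-fold. Among the 200 the test recovered 28% of genes changed 2-fold and 77.8% of genes changed 4-fold. Of 121 calls, 5.79% were unchanged genes. The real pairs differed in spread (SD 0.305 in log2 CPM in the controls, 0.664 in the CD19 DKO pair). Far more genes were called in the data, so these shares may not hold there.

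Before the data were examined, 38 gene lists were fixed, with markers of other cell types among them. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at its preset correlation of 0.01 on log2 CPM (prior count 2), against all other tested genes, with p adjusted over 35 lists. Genes were named by a rule also fixed then. It takes the targeted and construct genes, the 12 largest rises and the 12 largest falls among called genes with a mean log2 CPM of at least 2 and both libraries labelled CD19 DKO beyond both controls, and, for each list, up to 4 called members with the largest change at a mean log2 CPM of at least 1, or, where no such member was called, up to 2 members with the highest mean expression; 146 of the 150 genes so named were called. Predicted genes, pseudogenes and sex-linked genes were left out of the largest changes. Pttg1, Top3b, Eif2s3y and Uty lie outside the rule and were named after their values were seen.

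Alternatives were DESeq2-style size factors, upper-quartile factors and library totals in the same fit, DESeq2 1.42.0, limma-voom, no filter, a stricter filter (at least 50 counts in 2 libraries), the replicate number as a block, each library left out in turn, and stricter thresholds. For the lists they were an estimated correlation, fry and voom weights. Removing the immunoglobulin genes was planned and not run, since the table has none. Genes were placed on GRCm38 with the GENCODE M21 and RefSeq annotations by symbol; 12040 of the 12068 tested genes had a chromosome and 11995 a transcript GC content. The share of a gene's exon bases that lie in exons of other genes was computed for named genes, since the strand setting is unknown. Chromosome medians use genes with a mean log2 CPM above 3. Figures were drawn with matplotlib 3.10.9.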

Results

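RNA was sequenced from splenic B cells of 10-week-old C57BL/6J mice, in 4 libraries from 2 genotype groups. The group labelled CD19 DKO (n = 2 libraries) came from flow-sorted YFP-positive B cells; the series description names Tet2 and Tet3 as the genes of the DKO. The group labelled Dfl (n = 2), called control here, came from sorted CD19-positive, YFP-negative B cells, so the sort gate differed between the groups along with the genotype. Tet2 and Tet3 encode dioxygenases that oxidise 5-methylcytosine in DNA. The series title places the comparison in a study of how TET loss relates to oncogenesis, DNA damage, G-quadruplexes and R-loops. Library totals were close to each other, at 23869809 and 22963828 counts in the controls and 22913961 and 23273016 in the libraries labelled CD19 DKO. Genes with at least 1 count numbered 13751 and 13814 in the controls and 14096 and 14498 in the others. The labels do not say whether the samples of a group came from separate animals, so the p-values measure only the spread between these samples. A count of 0 in 1 library allows up to 0.126 to 0.132 CPM (counts scaled to a library total of 1e+06 after TMM factors), counting error only.

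The targeted genes were read first. Tet3 counts fell in both libraries labelled CD19 DKO, from 251 ± 2.0 CPM in the controls to 113 ± 24.8 CPM (SD, n = 2 each; log2 fold change -1.15, SE 0.18, edgeR adjusted p = 0.018). Tet2 counts went the other way and rose, from 112 ± 4.1 CPM to 267 ± 38.4 CPM (log2 1.25, SE 0.14, adjusted p = 0.010). The counts cover the whole of each gene: Tet2 spans positions 133463677 to 133545136 of chromosome 3 and Tet3 positions 83362373 to 83457208 of chromosome 6 (GRCm38, both on the minus strand), and the longest transcript with a consensus coding sequence has 11 exons in each. Reads from exons outside a deleted part are counted too, so the Tet2 and Tet3 values neither measure the deletion nor check the labels, and every direction below is that of the libraries as labelled. Tet1, the other member of the family, was low and fell further, from 8.23 ± 0.35 to 2.24 ± 0.49 CPM (log2 -1.87, SE 0.34, adjusted p = 0.023). Cd19, which encodes a B cell co-receptor and whose locus drives Cre recombinase in a widely used B cell deleter line, fell from 2421 ± 105 to 1047 ± 336 CPM (log2 -1.21, SE 0.26, adjusted p = 0.033). The transcript of the Rosa26 locus, Gt(ROSA)26Sor, where reporters are often inserted, rose from 3.85 ± 0.74 to 14.7 ± 4.8 CPM (log2 1.93, SE 0.36, adjusted p = 0.025); 8.55% of its exon bases lie in exons of a gene on the opposite strand.

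**Figure D1:**
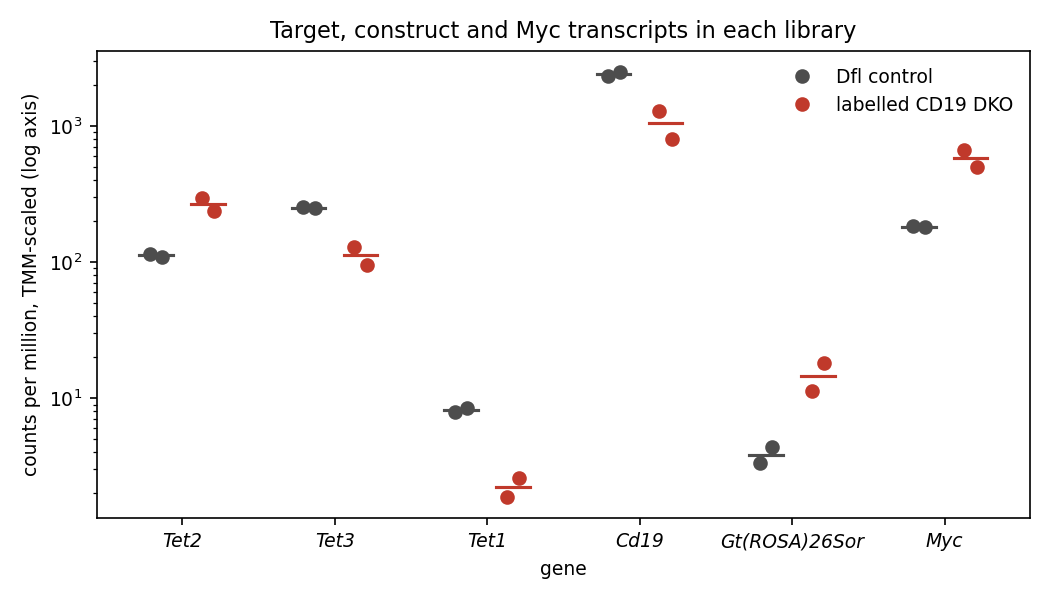
TMM-scaled CPM (log axis) of Tet2, Tet3, Tet1, Cd19, Gt(ROSA)26Sor and Myc in each of the 4 libraries; points are libraries and bars are group means. Both libraries labelled CD19 DKO lie above both controls for Tet2 (294 and 240 against 115 and 109 CPM) and below both for Tet3 (130 and 95.1 against 252 and 249 CPM).

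Transcription differed broadly between the groups. Of 12068 genes tested, 3870 changed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 2074 of them higher and 1796 lower in the libraries labelled CD19 DKO, and 2126 by at least 2-fold. Several of the largest rises were in genes with no counts in either control. Iglon5, a cell adhesion gene, reached 30.6 ± 11.0 CPM and was at least 471-fold higher, taking 3 counts over the control group as the floor. By the same floor Stard13, a Rho GTPase-activating protein gene, was at least 298-fold higher (34.3 and 4.11 CPM; at least 63.1-fold without replicate 1 of the CD19 DKO label), Klhl13 at least 247-fold (25.7 and 6.18 CPM; at least 95-fold without it), Trim40 at least 183-fold and Nos2, the inducible nitric oxide synthase, at least 159-fold. Fbn2, which encodes the extracellular matrix protein fibrillin-2, went from 0.149 ± 0.21 to 363 ± 79.1 CPM, and Wipf3 from 0.262 ± 0.13 to 239 ± 228 CPM (78.3 CPM in replicate 1, the value without replicate 2). Foxp2, Atoh8, Nos1 and Lipg had 1 count over both controls. Their counting intervals put the ratios at 173 to 38222, 119 to 26297, 98.1 to 21713 and 86.6 to 19188. Foxp2 had 788 and 195 counts in the libraries labelled CD19 DKO. Tnfsf4, encoding OX40 ligand, had 1 and 4 counts in the controls and 79 and 1652 in the libraries labelled CD19 DKO.

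The largest falls included receptors of mature B cells. Ccr6, a chemokine receptor, fell from 145 ± 15.5 to 1.72 ± 0.66 CPM (log2 -6.39, SE 0.32, adjusted p = 0.0042). Cr2, the complement receptor CD21, fell from 1177 ± 172 to 36.9 ± 6.4 CPM (log2 -5.00, SE 0.22), and the sphingosine-1-phosphate receptor gene S1pr3 from 58.2 ± 7.8 to 1.49 ± 0.087 CPM. Ryr2 had 214 and 300 counts in the controls and 3 and 0 in the other libraries, a ratio with a counting interval of 0.001 to 0.017. The other genes among the 12 largest falls were Tspan15 (log2 -5.59), Trps1 (-5.45), Pxdc1 (-5.40), Rapgef4 (-5.07), Pglyrp2 (-4.96), Emid1 (-4.87), Maml3 (-4.80) and Cpm (-4.77). The libraries labelled CD19 DKO differed in Tspan15 (0 and 12 counts), Pxdc1 (5.31 and 2.55 CPM) and Emid1 (0.716 and 2.64 CPM). Exons of genes on the opposite strand cover 14.5% of the exon bases of Pglyrp2 and 10.5% of those of Pxdc1. Leaving out either control library ended every gene call, those of Tet2 and Tet3 included: edgeR called 0 genes without control replicate 1 (2636 at an unadjusted p under 0.05) and 0 without control replicate 2 (2738), with the lone control assumed to vary like the other group and no other tool run. Without replicate 1 or replicate 2 of the CD19 DKO label it called 7945 and 7313 genes, with the lone library assumed to vary like the control pair, whose SD (0.305 in log2 CPM) was below that of the CD19 DKO pair (0.664), so these counts are no measure of how many genes changed.

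Genes of the cell cycle rose. Of 38 gene lists, 35 had enough tested members for a list test and 19 passed it, 13 upward and 6 downward. In the list of mitosis and G2/M genes, 54 of 56 tested members rose and 1 (Pttg1) fell, with the highest median log2 fold change of these lists (3.63); adjusted over the list alone the counts were again 54 and 1. Nuf2, a kinetochore gene, rose from 1.26 ± 0.40 to 46.5 ± 2.0 CPM, and cyclin B1 (Ccnb1) from 0.194 ± 0.087 to 9.12 ± 3.96 CPM. Pbk (log2 4.91) and Hmmr (4.79) were the other largest. Of 53 DNA replication and G1/S genes, 48 rose and none fell (50 adjusted over the list alone), with a median of 2.16. Mcm10, which loads replication factors, rose from 2.59 ± 0.34 to 71.4 ± 18.6 CPM, and Dtl from 3.95 ± 0.34 to 79.3 ± 10.6 CPM. Both lists passed the camera test against all other genes at its preset correlation of 0.01 (adjusted p = 3.54e-24 and 2.14e-21). With the correlation estimated for each list neither passed (adjusted p = 0.539 and 0.507 with an estimated correlation), nor did any of the other 17 lists. In that setting camera takes its degrees of freedom from the 4 libraries, so hardly any list could pass after adjustment. Its lowest unadjusted camera p was 0.046, for the B-1 list. No conclusion about a list is drawn from that setting.

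Myc, which encodes a transcription factor that drives growth, rose from 182 ± 2.4 to 585 ± 122 CPM (log2 1.69, SE 0.18, adjusted p = 0.0093). It lay within a list of MYC targets and ribosome biogenesis genes of which 40 of 50 rose and none fell (43 adjusted over the list alone; mean log2 fold change 1.01, camera adjusted p = 1.90e-14, and adjusted p = 0.550 with an estimated correlation). Odc1, the first enzyme of polyamine synthesis, rose from 30.8 ± 1.9 to 146 ± 3.8 CPM, and Srm, spermidine synthase, from 37.8 ± 2.2 to 144 ± 14.6 CPM. Of 49 oxidative phosphorylation genes 29 rose and none fell (38 adjusted over the list alone; median 0.71, adjusted p = 2.26e-09, and adjusted p = 0.763 with an estimated correlation), Atp5g3 and Uqcrq each with a log2 fold change of 1.15. Of 52 cytosolic ribosomal protein genes 6 rose, 0 adjusted over the list alone, with a median of 0.48 (adjusted p = 4.74e-05, and adjusted p = 0.771 with an estimated correlation). Many ribosomal protein genes have near-identical pseudogene copies, so their counts are uncertain. Glycolysis genes went both ways, 7 up and 6 down of 25 (adjusted p = 0.182, and 0.0497 without replicate 1 of the CD19 DKO label; 11 and 6 adjusted over the list alone), with Hk2 up (log2 2.14) and the glucose transporter gene Slc2a3 down (-2.27).

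**Figure D2:**
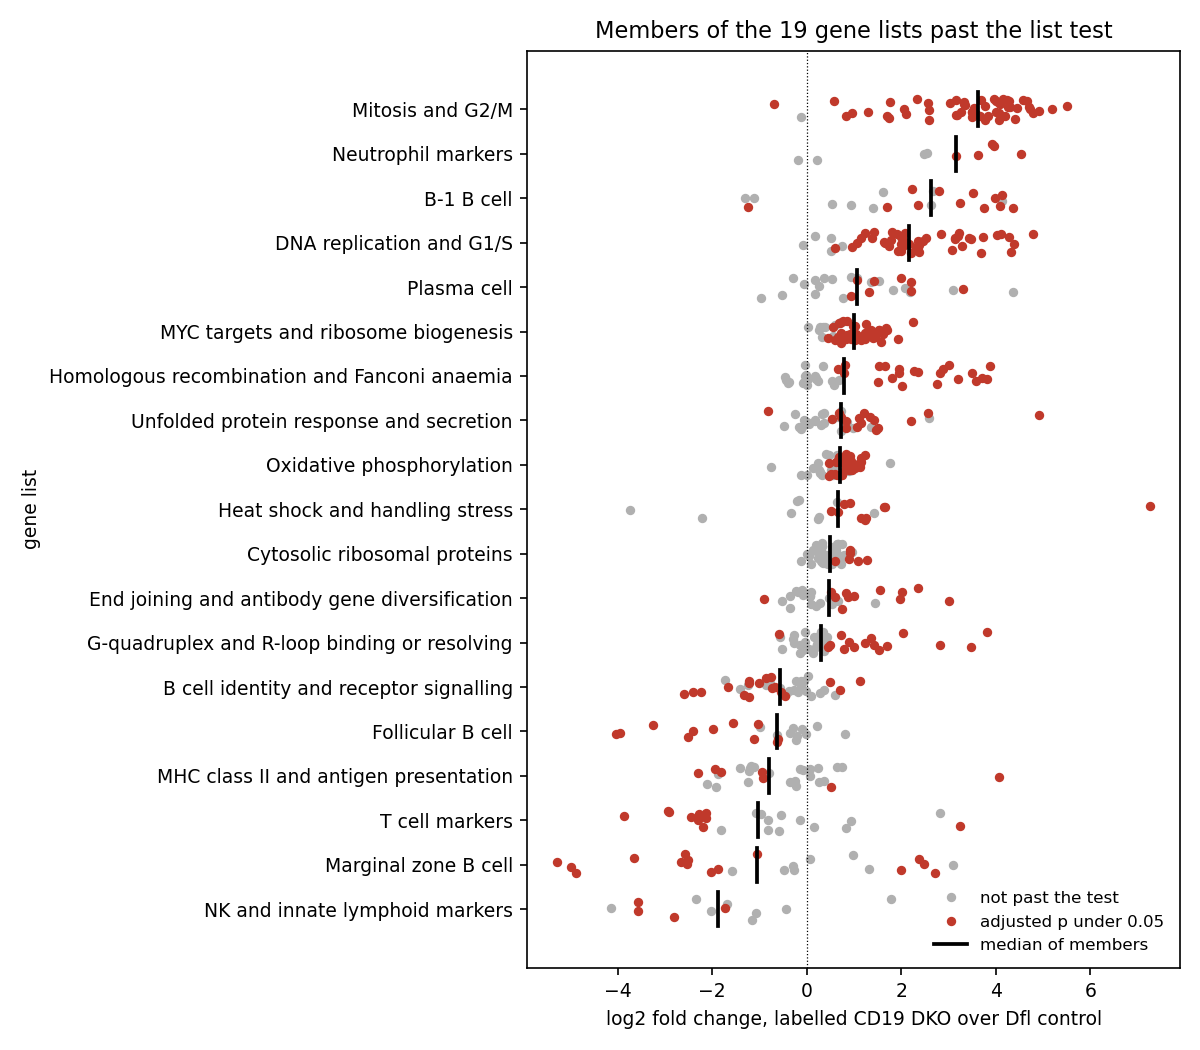
Log2 fold change (libraries labelled CD19 DKO over controls) of every tested member of the 19 gene lists that passed the camera test at the preset correlation; each point is a gene, red where it passed the gene test, and black bars are list medians. Mitosis and G2/M genes have the highest median (3.63) and natural killer and innate lymphoid markers the lowest (-1.88).

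Genes that act on DNA damage and on unusual nucleic acid structures rose in part. Of 41 homologous recombination and Fanconi anaemia genes, 22 rose and none fell (25 and 1 adjusted over the list alone; median 0.79, camera adjusted p = 6.97e-06, and adjusted p = 0.507 with an estimated correlation). Chek1, a checkpoint kinase, rose from 2.14 ± 0.29 to 31.6 ± 4.6 CPM. In the list of proteins that bind or resolve G-quadruplexes and R-loops, 15 of 40 rose, 1 (Top3b) fell and 24 did not pass (16 and 3 adjusted over the list alone; median 0.31, adjusted p = 0.0024, and adjusted p = 0.550 with an estimated correlation). The largest were the helicase genes Brip1 (2.73 ± 0.24 to 38.5 ± 8.0 CPM), Pif1 (1.76 ± 0.50 to 19.6 ± 4.5 CPM) and Recql4 (7.22 ± 2.3 to 29.5 ± 9.9 CPM) and the Fanconi gene Fancd2 (5.0 ± 0.71 to 35.6 ± 10.5 CPM). These also act in DNA replication or repair, and 4 members belong to the homologous recombination list too. Some other members also belong to the DNA replication list or the MYC list. Of 29 end joining and antibody diversification genes, 11 rose and 1 fell (13 and 2 adjusted over the list alone; adjusted p = 0.020, and adjusted p = 0.763 with an estimated correlation). Exo1 (log2 3.01) and the uracil glycosylase gene Ung (2.36) had the highest values among those that rose, followed by H2afx (2.02; 10.2% of its exon bases lie in exons of another gene) and the ligase gene Lig4 (1.98; 81.0 and 34.0 CPM in the libraries labelled CD19 DKO). The list did not pass without replicate 1 of the CD19 DKO label (adjusted p = 0.137). The p53 target list did not pass (adjusted p = 0.238): 10 of 39 rose and 5 fell (13 and 6 adjusted over the list alone), among them Cdkn1a, the cell cycle inhibitor p21, up from 2.97 ± 1.6 to 17.7 ± 7.0 CPM. The DNA methylation and TET list did not pass either (adjusted p = 0.892, downward, with a median of -0.10 and a mean of 0.10); 5 of 20 rose and 5 fell (5 and 6 adjusted over the list alone). Uhrf1, which recruits the maintenance methyltransferase, rose from 23.8 ± 3.8 to 210 ± 25.8 CPM and the chromatin remodeller gene Hells from 11.5 ± 0.98 to 124 ± 30.0 CPM, while the TET inhibitor gene Cxxc5 fell from 138 ± 9.8 to 32.7 ± 17.4 CPM (45.0 and 20.4 CPM). Uhrf1, Hells and Ung also belong to the DNA replication list, and Exo1 to the homologous recombination list, so their rises are not separate results.

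Part of the genes of resting B cell subsets fell. Of 40 B cell identity and receptor signalling genes, 15 fell, 3 rose and 22 did not pass (18 and 3 adjusted over the list alone; median -0.56, camera adjusted p = 0.00065, and adjusted p = 0.507 with an estimated correlation). Bank1, a scaffold of receptor signalling, fell from 748 ± 4.9 to 124 ± 0.59 CPM, and the inhibitory receptor gene Cd22 from 3169 ± 43.5 to 670 ± 234 CPM. Of 21 follicular B cell genes 11 fell and none rose, also adjusted over the list alone (median -0.63, adjusted p = 0.00031, and adjusted p = 0.507 with an estimated correlation). Fcer2a, which encodes CD23, fell from 1755 ± 59.9 to 108 ± 24.7 CPM and the ligand gene Icosl from 628 ± 17.2 to 40.4 ± 17.0 CPM. Of 23 marginal zone genes 11 fell, with Cr2 and S1pr3 at the head, and 4 rose, also adjusted over the list alone (median -1.04, adjusted p = 0.012, and adjusted p = 0.527 with an estimated correlation). Among those that rose was Cd9 (15.6 ± 0.34 to 102 ± 45.2 CPM), of whose exon bases 10.7% lie in exons of other genes. This list did not pass without replicate 2 of the CD19 DKO label (adjusted p = 0.0651). Of 29 MHC class II and antigen presentation genes 5 fell and 2 rose (5 and 2 adjusted over the list alone; median -0.80, adjusted p = 0.040, and adjusted p = 0.804 with an estimated correlation), with H2-DMb1 down from 240 ± 1.1 to 48.7 ± 28.5 CPM and the co-stimulator gene Cd80 up (log2 4.07, SE 0.82). In replicates 1 and 2 of the CD19 DKO label H2-DMb1 had 28.6 and 68.9 CPM and Cd80 15.9 and 46.5 CPM. That list did not pass without replicate 1 of the CD19 DKO label (adjusted p = 0.0595) or with a stricter filter on low counts (0.0532).

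Part of the B-1 and plasma cell genes rose. Of 21 B-1 genes 11 rose and 1 fell (15 and 2 adjusted over the list alone; median 2.63, camera adjusted p = 0.00022, and adjusted p = 0.507 with an estimated correlation). Plscr1 rose from 5.21 ± 0.43 to 107 ± 36.3 CPM, Anxa2 from 12.8 ± 1.8 to 204 ± 108 CPM and the transcription factor gene Zbtb32 from 9.74 ± 3.3 to 167 ± 98.9 CPM. Cd5, a surface receptor of B-1a and T cells, rose from 8.65 ± 0.62 to 82.3 ± 27.2 CPM. Of 27 plasma cell genes 8 rose, none fell and 19 did not pass, also adjusted over the list alone (median 1.06, adjusted p = 0.0023, and adjusted p = 0.771 with an estimated correlation). Prdm1, which encodes the plasma cell regulator BLIMP1, rose from 4.31 ± 0.72 to 43.0 ± 31.2 CPM. Replicates 1 and 2 of the CD19 DKO label differed in Prdm1 (20.9 and 65.1 CPM), Anxa2 (128 and 280 CPM) and Zbtb32 (97.2 and 237 CPM). The list did not pass without replicate 2 of the CD19 DKO label (adjusted p = 0.192). Of 39 unfolded protein response and secretion genes 16 rose and 1 fell (17 and 1 adjusted over the list alone; median 0.72, adjusted p = 0.00064, and adjusted p = 0.763 with an estimated correlation), with the asparagine synthetase gene Asns up from 0.606 ± 0.11 to 18.5 ± 1.4 CPM and the degradation factor gene Derl3 up from 11.2 ± 1.1 to 51.9 ± 18.1 CPM. The germinal centre list did not pass (adjusted p = 0.054), with 9 of 26 up and 3 down (9 and 4 adjusted over the list alone). Its largest rises, Stil (log2 3.98) and Nek2 (3.80), are centrosome genes of dividing cells, and Efnb1 rose from 5.31 ± 0.46 to 69.6 ± 0.37 CPM. This list passed without control replicate 1 (adjusted p = 0.0287), with no filter (0.0457), with a stricter one (0.0352) and with a replicate block (0.0479).

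The other signalling and state lists did not pass. Of 24 atypical, age-associated and memory genes 8 rose and 5 fell (adjusted p = 0.821), with Nt5e, the ectonucleotidase CD73, up from 3.05 ± 0.57 to 76.5 ± 18.2 CPM. Of 39 activation and immediate early genes 9 rose and 6 fell (adjusted p = 0.719), with Ccnd2, cyclin D2, up (log2 2.42) and the mRNA decay factor gene Zfp36 down (-2.20). NF-kB targets had 7 up and 10 down of 32 (adjusted p = 0.932, downward, while the median was 0.03 and the mean 0.18), with lymphotoxin alpha (Lta) at -3.84. Interferon response genes had 4 up and 12 down of 46 (adjusted p = 0.074; 0.00235 without replicate 2 of the CD19 DKO label), with Ifit3 at -2.06 and Iigp1, a GTPase gene, up from 0.826 ± 0.14 to 100.2 ± 101 CPM. Nucleic acid sensing genes had 4 up and 3 down of 23 (adjusted p = 0.385), with Tlr3 at -4.12 and Rnaseh2b at 1.69. BCL2 family and apoptosis genes had 9 up and 5 down of 27 (adjusted p = 0.215), with Casp3 at 2.72. Immune checkpoint genes had 5 up and 6 down of 24 (adjusted p = 0.715, downward, with a median of -0.07 and a mean of 1.05), and Pdcd1, which encodes PD-1, rose from 0.388 ± 0.17 to 36.0 ± 28.0 CPM. Chemokine receptor, integrin and homing genes had 2 up and 7 down of 27 (adjusted p = 0.238). Of 12 V(D)J recombination and early B cell genes 3 rose and 1 fell (adjusted p = 0.627), with Myb up from 48.4 ± 1.3 to 620 ± 305 CPM and Cd93 up from 33.0 ± 3.6 to 278 ± 86.7 CPM. In replicates 1 and 2 of the CD19 DKO label Iigp1 had 28.5 and 172 CPM, Pdcd1 16.1 and 55.8, Casp3 68.8 and 186, Myb 835 and 405, Lta 2.40 and 8.30, and Tlr3 0.295 and 0.778. Replication-dependent histones had 2 up of 20, 0 adjusted over the list alone (adjusted p = 0.592, upward, with a median of -0.02 and a mean of 0.84). Only 20 of the 37 histone genes in the count table were tested, at low levels. Their summed CPM was 28.8 and 34.6 in the controls and 24.6 and 32.8 in the libraries labelled CD19 DKO. The list therefore does not tell whether histone genes changed. Adjusted over the list alone, the counts up and down were 8 and 6 for the atypical list, 9 and 7 for activation, 8 and 10 for NF-kB, 4 and 12 for interferon, 4 and 4 for sensing, 11 and 5 for BCL2, 7 and 7 for checkpoints, 2 and 7 for homing, and 3 and 1 for early B cells.

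Of the markers of other cell types, those of T cells, natural killer cells and neutrophils passed the list test. T cell markers fell in 9 of 22 tested genes, also adjusted over the list alone, with Itk down from 11.3 ± 0.58 to 0.769 ± 0.13 CPM and Zap70 from 6.16 ± 1.6 to 0.81 ± 0.11 CPM (median -1.02, camera adjusted p = 0.0071, and adjusted p = 0.771 with an estimated correlation). Summed over its tested members, this list had 502 and 441 CPM in the controls. Replicates 1 and 2 of the CD19 DKO label had 268 and 557 CPM, so replicate 2 lay above both controls. These sums include Cd5, at 9.09 and 8.21 CPM in the controls and 102 and 63.1 CPM in replicates 1 and 2. Since Cd5 is also a B-1a gene, the sums do not measure T cell RNA alone. Cd5 was the 1 member that rose, and without replicate 1 of the CD19 DKO label the list did not pass (adjusted p = 0.193). Natural killer and innate lymphoid markers fell in 4 of 12 (9 adjusted over the list alone; adjusted p = 0.0047, and adjusted p = 0.550 with an estimated correlation), with Gzma down from 5.61 ± 0.51 to 0.794 ± 0.47 CPM (0.463 and 1.12 CPM). Neutrophil markers rose in 5 of 9, also adjusted over the list alone (median 3.16, adjusted p = 0.014, and adjusted p = 0.771 with an estimated correlation), at low levels: S100a8 went from 6 and 4 counts to 63 and 178 and S100a9 from 13 and 9 to 124 and 217. That list did not pass without replicate 2 of the CD19 DKO label (adjusted p = 0.0685). Monocyte and macrophage markers (0 up and 2 down of 28, 0 and 0 adjusted over the list alone; adjusted p = 0.333) and dendritic cell markers (0 up and 2 down of 15, 0 and 1 adjusted over the list alone; adjusted p = 0.595) did not pass. Summed monocyte and macrophage markers had 446 and 405 CPM in the controls, against 346 and 681 in replicates 1 and 2 of the CD19 DKO label. The erythroid and platelet, stromal and endothelial, and sex-linked lists had 3, 3 and 4 tested members, too few for the list test. Car2 fell (log2 -3.28), Tfrc, also in the MYC list, rose (1.62) and Pecam1 fell (-1.08). Pecam1 had 420 CPM in each control, most of the summed 428 and 424 CPM of the stromal and endothelial list. Heat shock and handling stress genes rose in 10 of 19 and fell in none (10 and 1 adjusted over the list alone; median 0.67, adjusted p = 0.015, and adjusted p = 0.771 with an estimated correlation), among them Hsp90aa1 (59.9 ± 12.9 to 190 ± 9.0 CPM) and Hspd1 (68.0 ± 3.8 to 212 ± 11.9 CPM). Without replicate 1 or replicate 2 of the CD19 DKO label the heat shock list did not pass (adjusted p = 0.0595 and 0.0651).

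The libraries labelled CD19 DKO differed from each other more than the controls did. Over tested genes the SD between the pair was 0.664 in log2 CPM, against 0.305 between the controls. The first principal component, which parted the genotype labels, held 77.7% of the variance, and the second, which parted the CD19 DKO pair, held 18.4%. Genes on chromosome 15 stood at a median log2 ratio of 0.46 over the controls in replicate 2 of the CD19 DKO label and of -0.03 in replicate 1 (373 genes with a mean log2 CPM above 3). The other 18 autosomes had medians from -0.16 to 0.09 in replicate 2. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty kept 15.2%, 26.9%, 17.4% and 24.6% of their control level in replicate 2 and 78.6%, 92.1%, 83.8% and 89.4% in replicate 1. Without the tested genes of chromosomes 15 and Y, an alternative chosen after seeing the data, 3820 genes were called.

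**Figure D3:**
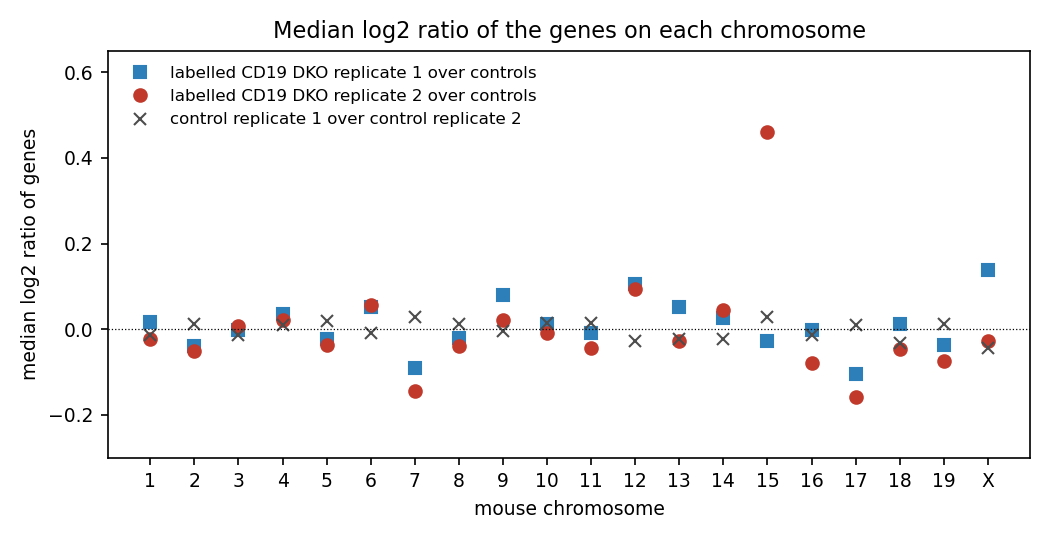
Median log2 ratio of the expressed genes on each autosome and on chromosome X, for each library labelled CD19 DKO over the control mean and for control replicate 1 over control replicate 2. Chromosome 15 in replicate 2 of the CD19 DKO label lies at 0.46; the other autosomes of that library lie between -0.16 and 0.09, and those of the control pair between -0.03 and 0.03.

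The authors' deposited table of the same comparison lists 4890 genes at an adjusted p under 0.05, 2778 higher and 2112 lower in CD19 DKO. Of the 3870 genes called here, 3838 were called in the authors' deposited table too, all 3838 in the same direction. Both sets of calls rest on the same counts, so the shared direction is no independent support. The authors' called genes that were tested here numbered 4799.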

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

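The alternative without genes of chromosomes 15 and Y was chosen after the data were seen; the others were planned. Of the 3870 genes changed (2074 higher, 1796 lower), 755 had an adjusted p under 0.01 (458 higher, 297 lower) and 2126 changed at least 2-fold (1206 higher, 920 lower), by construction fewer. With a replicate block 2609 genes passed, 1472 higher and 1137 lower, and 2523 of the 2609 were among the 3870; the replicate numbers do not pair the libraries in the data (correlation of deviations over genes -0.069). Leaving out each library in turn gave 0 to 7945 genes, 0 to 4130 higher and 0 to 3815 lower; edgeR called 0 without control replicate 1 (2636 at an unadjusted p under 0.05) and 0 without control replicate 2 (2738), where the spread rests on the CD19 DKO pair, whose SD (0.664 in log2 CPM) exceeds that of the controls (0.305). The other scalings (3838, 3877 and 3766 genes), no filter (3439), the stricter filter (3970), DESeq2 (4888), limma-voom (3733) and the fit without chromosomes 15 and Y (3820) stayed within 1.5 times the count. Of the 150 genes named by the rule, none changed direction under the alternatives that tested it; the fit without chromosomes 15 and Y tested 144 of them and the stricter filter 149, and genes named outside the rule were not run. Of the 146 that passed, voom left out 22, the replicate block 17, no filter 3 and upper-quartile scaling 1; the cause was not tested. Of the 19 lists called (13 up, 6 down), 0 passed with an estimated correlation (0 up, 0 down). The B-1, marginal zone and B cell identity lists had estimated correlations of -0.028, -0.033 and -0.0024. These lie below the preset 0.01, so a higher correlation did not end those calls. The other called lists had estimated correlations above 0.01. Examples are 0.381 for mitosis and G2/M, 0.375 for MYC targets, 0.483 for oxidative phosphorylation and 0.551 for MHC class II. For lists with such correlations the camera p at the preset would be too small. With fry, which tests each list without comparing it with other genes, 9 passed (6 up, 3 down), and the cause was not tested. Leaving out each library gave 16 to 20 lists, 10 to 14 up and 4 to 6 down. A count of 0 allows up to 0.132 CPM in the shallowest library after scaling. Removing immunoglobulin genes was not run, as the table has none.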

Other observations

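The genes of this paragraph were picked after their values were seen. Cdkn2a, whose locus encodes the cell cycle inhibitor p16 and the p53 activator ARF, which gene counts do not tell apart, had 0 and 6 counts in the controls and 505 and 806 in the libraries labelled CD19 DKO (log2 fold change 7.69, edgeR adjusted p = 0.013). Trp53 itself (log2 -0.18, adjusted p = 0.243) and Mdm2 (0.11, adjusted p = 0.639) did not pass. Phgdh had 30.8 and 31.3 CPM in the controls against 236 and 199 (log2 2.81, adjusted p = 0.0040), and Psat1 21.8 and 28.6 against 160 and 151 (log2 2.62, adjusted p = 0.0047). Actn1, an actin crosslinker, had 22.1 and 17.0 CPM in the controls against 669 and 947. Ahr, the aryl hydrocarbon receptor, had 13.0 and 14.5 CPM against 116 and 91.6. Among genes that fell, Neurl3 had 308 and 281 CPM in the controls against 13.7 and 11.8, and Ablim1 1078 and 1075 against 152 and 163. Bach2 (log2 -1.03), S1pr1 (-1.56), Cxcr5 (-1.11) and Foxo1 (-0.74), regulators of B cell maturation, migration and quiescence, also fell, while Pax5, the B lineage factor, did not pass (-0.83, adjusted p = 0.057).

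The libraries labelled CD19 DKO held unlike levels of some genes, also picked after the values were seen. Cd74, the MHC class II invariant chain, had 2952 CPM in replicate 1 and 8973 in replicate 2, against 16242 and 15288 in the controls, and Ciita, which drives its transcription, 104 and 331 against 825 and 822. Jchain, which encodes the joining chain of secreted antibody, had 17.6 CPM in replicate 1 and 715 in replicate 2, against 47.5 and 38.0. Kit had 2.65 and 133 CPM and Itgam 8.55 and 104. Adm went the other way, with 380 CPM in replicate 1 and 39.9 in replicate 2, as did Gad1, with 137 and 4.54. Ebf1, a B lineage factor, had 258 and 65.9 CPM, against 399 and 369 in the controls.

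Of the tests below, those of Xist, of the Y-linked genes, of the scaling of Tet2 and of exchanged labels were chosen only after the result was seen, and all 3 patterns were noticed in these data. Chromosome 15 in replicate 2 of the CD19 DKO label had a median log2 excess over the other autosomes of 0.49 (95% bootstrap interval 0.37 to 0.62, 1.41-fold, 373 genes), and none of 10000 random gene lists matched on expression came as high. GC content did not account for it, since the excess was 0.51 (0.42 to 0.63) after correction, and nor did a few strongly raised genes, since 72.4% of the genes (95% interval 67.5 to 76.9) lay above the median of the other autosomes. A candidate explanation is an extra copy of the chromosome in many of the cells. Along the chromosome the excess was 0.68 (0.51 to 0.95), 0.43 (0.28 to 0.73) and 0.33 (0.12 to 0.51) in 3 position blocks of near equal gene number. The prediction set before this test for an extra copy was an excess of at least 0.3 in each block. All 3 blocks met it, though the intervals of the later blocks reached below it. The point values fell from block to block, while a whole extra copy alone would give like values in all blocks. Whether the blocks differ was not tested. No DNA was sequenced here, and a biological explanation by genotype was not tested, since replicate 1 had an excess of -0.02.

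The 4 Y-linked genes kept 15.2% to 26.9% of the control level in the same library. Female cells mixed into it would bring Xist, which had 10 counts there (Poisson interval 4.80 to 18.4) against a mean of 5.67 in the other 3 libraries, a ratio of 1.76 that argues against them. Loss of the Y chromosome from part of the cells stays open: it predicts like shares for all 4 genes, and the highest share was 1.78 times the lowest, a spread that fewer transcripts from an intact Y could give too. No biological explanation by genotype was tested, as replicate 1 kept 78.6% to 92.1%.

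Tet2 counts were higher, not lower, in the libraries labelled CD19 DKO. Scaling did not make this, as the log2 fold change lay between 1.23 and 1.30 over 4 scalings, and nor did an overlapping gene, as 0.25% of Tet2 exon bases lie in exons of another gene. Exchanged labels cannot be told apart from the labels as given, since whole-gene counts do not read the deleted exons. Tet3 (log2 -1.15) and Cd19 (-1.21) were lower, which goes with the labels as given, but cell state also sets their levels. No direction was predicted for Gt(ROSA)26Sor (1.93), so its rise says nothing about the labels. A more abundant Tet2 transcript that lacks exons was not tested, as it needs reads per exon.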
